A study of Arabidopsis thaliana with 15 samples.

How the data were processed

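Native ChIP-seq and MNase-seq libraries came from 8-day-old seedlings of Arabidopsis thaliana Col-0, with input chromatin, total H3, H3K4me2, H3K4me3 and H3K36me3 in wild type, fpa and bdrs plants, 15 libraries with 1 per assay and genotype. For 1 input library of the bdrs mutant the source name gives an age of 7 days and the age field 8 days. Samples were grouped by mark and genotype from the labels. The processed data were 3 peak lists, 1 per mark, which the labels name for the wild-type, fpa and bdrs libraries of that mark together.

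Per the submitters' processing notes, Trimmomatic 0.33, Bowtie2 2.2.6, Picard 2.2.4, SAMtools 1.3, R 3.3.2 and MACS2 were used with the TAIR10 genome. The notes give no role, order or setting for these tools, no version for MACS2, and no account of the selection of peaks. The peak names in the deposited files say that each list was called on pooled libraries of the mark against pooled H3 libraries. The lists have the narrowPeak layout of MACS2, and the values fit it. The deposited fold enrichment is the caller's ratio of the mark over pooled H3, and the −log10 p and −log10 q columns are the caller's. The deposited score is 10 times the −log10 p cut to a whole number. The peak numbers run in genomic order with gaps, so called peaks were left out before deposit: the lists keep 62.8% of 36905 numbers for H3K4me2, 76.3% of 23175 for H3K4me3 and 62.8% of 21492 for H3K36me3. How these were chosen is not given in the sources used here. A called peak that was left out counts as no peak here, and a gene without a listed peak can hold a weaker one.

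Which libraries were pooled, and whether they include all 3 genotypes, is not stated in the sources used here, and no difference between genotypes, replicate error or depth per library can be taken from the lists. The intervals given are 95% percentile intervals from 1000 bootstrap draws of 1 Mb genome blocks, which cover the variation along this genome and not that between plants. Total H3 was the control. The H3K4me3 peaks on FRI and MAF3 nonetheless share a fold of 11.4226 and a −log10 p of 525.641. Whether each fold is set against local H3, and so is an enrichment per nucleosome, therefore cannot be told.

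Peaks were set on the 27444 nuclear protein-coding genes of the NCBI RefSeq gene table for assembly TAIR10.1, while the lists are on TAIR10. No coordinate of that table is printed, and every coordinate in the text is a peak's own, counted from 1. Whether both run in the same register was checked on the data: the share of peak sequence inside genes was highest with no offset, at 93.5%, 96.2% and 98.3% for H3K4me2, H3K4me3 and H3K36me3, and lower at every offset of 100 bp to 1000 bp tried to either side. In 118 blocks of 1 Mb, the best offset among steps of 100 bp was 0 in 112, 117 and 116 blocks for the 3 marks. Shifts under 100 bp would not be seen by this check. The table gives no strand and no class of transposable element genes. Planned distances from the transcription start were therefore replaced by the distance to the nearer gene end, and by the position from the end nearer the H3K4me3 summit in 14662 genes whose only H3K4me3 summit lay in an outer part of the gene, and pseudogenes replaced transposable element genes.

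A gene carried a mark where peaks covered at least 200 bp of its body, or 50% of it in genes shorter than 400 bp. Overlap of peaks meant at least 1 bp and was set against 1000 rotations of 1 list along each chromosome (two-sided permutation test, Benjamini-Hochberg adjustment over 6 shares). Combinations of marks were compared with 1000 independent placements within deciles of gene length. Gene lists of 190 genes fixed before the data were examined, and 48 ribosomal protein genes recognised by their names in the gene table, were compared with 10000 random lists matched on gene length decile (two-sided permutation test, smallest p 2.00e-04, adjustment over 36 pairs of 12 lists and 3 marks, of which 16 passed 0.05, with 7 shares higher and 9 lower). Genes are not replicates of a condition, so these tests describe the lists. The rules for naming genes were also fixed beforehand: the study genes and FLC, the 8 genes with a symbol and the highest −log10 p and the 3 with the widest peaks per mark, and the members of a list outside its majority state or the first 4 of each state. A result that these rules select for the widest peaks and a gene family are not reported here. The symbols of 3 BDR loci, AT5G25520, AT5G11430 and AT2G25640, are not in the gene table, and they go by identifier. Their assignment as BDR genes was made from recall before the data were examined and rests on no source used here. Gene families in the closing section were formed from symbols with a shared prefix and at least 20 members after the data were seen.

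The tests were tried on simulated data. With randomly placed peaks, 2 of 20 simulated sets passed 0.05 for H3K4me3. Planted overlaps were copies of part of the same list, so their error of 0 percentage points was fixed by construction. Of 100 lists of 20 genes with 19 carriers of H3K4me3 each, 99 passed, and of 100 random lists of 20 genes 6 did. The alternatives tried, each for the results it concerns, were the strongest 50% of each list, merged peaks, overlap of 50% of a peak, rotation along gene-containing sequence, each chromosome left out, other rules for carrying a mark, peak midpoints, long or isolated genes, unmatched random lists, 250 kb blocks and, chosen after the data were seen, equal numbers of peaks per list and the fold in place of −log10 p. The input libraries were not used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.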

Results

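Native ChIP-seq, in which chromatin is cut with micrococcal nuclease (MNase) and not crosslinked, was carried out on whole seedlings of Arabidopsis thaliana, accession Col-0, at 8 days of age. The series held 15 libraries, with input chromatin, total histone H3, H3K4me2, H3K4me3 and H3K36me3 each profiled in wild type, in a mutant of FPA and in a triple mutant of the BDR genes. FPA encodes an RNA-binding protein that acts in RNA 3′ end formation and in the control of flowering time. Each mark was sequenced in 1 library per genotype. The data analysed here were 3 lists of peaks, 1 for each methylation mark, called on pooled libraries against pooled total H3 and named by the labels for the 9 libraries of the 3 marks. Which genotypes were pooled is not stated. The lists carried no value for a single genotype, so the comparison of the mutants with wild type is not analysed here and the comparisons below are between marks. There was no replicate error, and the read depth behind the peaks is unknown.

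H3K36me3 formed the widest domains and H3K4me3 the narrowest. The median peak width was 1623 bp for H3K36me3 (95% interval over resampled genome blocks 1606 to 1640), 981 bp for H3K4me2 (966 to 994) and 834 bp for H3K4me3 (825 to 842). H3K4me2 had the most peaks, 23189, against 17686 for H3K4me3 and 13491 for H3K36me3. Peaks covered 24.6 Mb with H3K4me2, 16.6 Mb with H3K4me3 and 25.8 Mb with H3K36me3, or 20.6%, 13.9% and 21.6% of the span of the 5 nuclear chromosomes. The widths held the same order on all 5 chromosomes, with medians of 1572 to 1642 bp for H3K36me3, 932 to 994 bp for H3K4me2 and 818 to 841 bp for H3K4me3. Summits fell inside protein-coding genes for 97.7% of H3K36me3, 95.9% of H3K4me3 and 92.7% of H3K4me2 peaks, while such genes made up 54.1% of the span. The authors' median fold enrichment over total H3 was 8.84 for H3K4me3, 5.68 for H3K36me3 and 3.37 for H3K4me2, and these folds rank peaks only within their own list. The weakest peak kept had a −log10 p of 8.58 in the H3K4me2 list, 38.5 in the H3K4me3 list and 55.2 in the H3K36me3 list, so the lists do not share a threshold and their peak numbers cannot be read as amounts of a mark.

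The strongest H3K4me3 and H3K36me3 peaks lay partly on the same genes. JAZ12, a repressor of jasmonate signalling, held the peak with the highest −log10 p among single genes with a symbol in both lists, with an H3K4me3 peak on chromosome 5 from 7090741 to 7091721 (TAIR10) at a fold of 15.0 and an H3K36me3 peak from 7090766 to 7092203 at a fold of 10.6. AKINBETA1, a subunit of the SnRK1 kinase, and PFN2, a profilin that binds actin, were also among the first 8 of both lists, with H3K4me3 folds of 14.9 and 14.4 and H3K36me3 folds of 10.3 and 10.0. The other H3K4me3 genes among the first 8 were ASP3, HSL1, LPPgamma and the brassinosteroid response factors BZR1 and BES1. For H3K36me3 they were VPS46.2, SIRANBP, TRIP-1, RBP45B and GRF6. The first 8 genes for H3K4me2 were CYP94C1, which oxidises the jasmonate hormone, NAC004, ATK4, the auxin-conjugating enzyme gene DFL1, VPS24.2, TTL2, PLL1 and PAB6, with folds of 11.1 to 13.4, and none of them was among the first 8 of the other lists. The widest H3K36me3 peak covered 25621 bp of ATM, the kinase of the DNA damage response, on chromosome 3 from 17801302 to 17826922, followed by peaks of 15493 bp on ILA and 14468 bp on SYD, a chromatin remodeller. Wide H3K4me3 peaks lay on BGAL1 (4401 bp) and GLT1 (4247 bp), and the widest H3K4me2 peaks on genes with a symbol lay on IRE (5929 bp, over 2 genes), chr31 (5301 bp) and the DNA methyltransferase gene CMT3 (5223 bp).

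Peaks of the 3 marks coincided more often than shifted peaks did. Nearly every H3K36me3 peak, 99.8% of 13491, overlapped an H3K4me3 peak by at least 1 bp, against a mean of 36.7% when the peaks were rotated along their chromosomes. The reverse share was lower, as 76.1% of H3K4me3 peaks overlapped H3K36me3 (31.2% when rotated). H3K4me2 was found at 94.5% of H3K4me3 peaks (36.7% when rotated) and at 94.5% of H3K36me3 peaks (47.7% when rotated). Of the H3K4me2 peaks, 73.1% overlapped H3K4me3 (28.1% when rotated) and 56.0% overlapped H3K36me3 (32.2% when rotated), so 26.9% of H3K4me2 peaks lay apart from H3K4me3. All 6 shares exceeded all 1000 rotations (two-sided permutation test, p = 9.99e-04, the smallest the rotations can give, and adjusted p = 9.99e-04). When 50% of the peak had to be covered, 55.9% of H3K36me3 peaks overlapped H3K4me3 and 69.0% overlapped H3K4me2 (10.1% and 17.5% when rotated). Keeping fewer peaks lowers these shares by construction, so the next values do not tell whether the overlap with H3K4me2 rests on weaker peaks. Among the strongest 50% of each list, H3K4me2 was at 44.3% of H3K4me3 peaks (20.9% when rotated) and 38.3% of H3K36me3 peaks (29.0% when rotated). In that set, 34.2% and 22.4% of H3K4me2 peaks overlapped H3K4me3 and H3K36me3 (16.0% and 18.4% when rotated). With equal numbers of peaks per list, H3K4me2 was at 58.8% of H3K4me3 and 57.6% of H3K36me3 peaks. In base pairs the overlap was partial, with a Jaccard index of 0.482 for H3K4me2 and H3K4me3, 0.410 for H3K4me3 and H3K36me3, and 0.390 for H3K4me2 and H3K36me3.

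On genes, the marks formed few of the possible combinations. Of 27444 nuclear protein-coding genes, 20582 carried H3K4me2, 17194 H3K4me3 and 13697 H3K36me3, where a gene carried a mark if peaks covered at least 200 bp of its body. All 3 marks together were found on 12778 genes (46.6%, 95% interval 45.1 to 47.8), which was 1.52 times the number from marks placed independently among genes of like length. No mark was found on 5871 genes (21.4%, 19.7 to 23.3), against 2790 placed independently. The intermediate states were H3K4me2 alone on 4187 genes, H3K4me2 with H3K4me3 on 3546 and H3K4me3 with H3K36me3 on 727. H3K36me3 without H3K4me3 was rare under this rule, with 121 genes for H3K36me3 alone and 71 for H3K36me3 with H3K4me2, or 0.137 and 0.0241 times the independent numbers. Of the genes with H3K36me3, 98.6% carried H3K4me3, while 78.5% of the genes with H3K4me3 carried H3K36me3. Genes with all 3 marks were longer, with a median of 2603 bp against 1717 bp for H3K4me2 alone and 1153 bp for genes with no mark. These shares depend on the rule, since requiring 50% of the gene body left 9420 genes with H3K4me2 and 5227 with H3K4me3, and H3K36me3 without H3K4me3 was then common, alone on 6301 genes and with H3K4me2 on 2000.

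**Figure D1:**
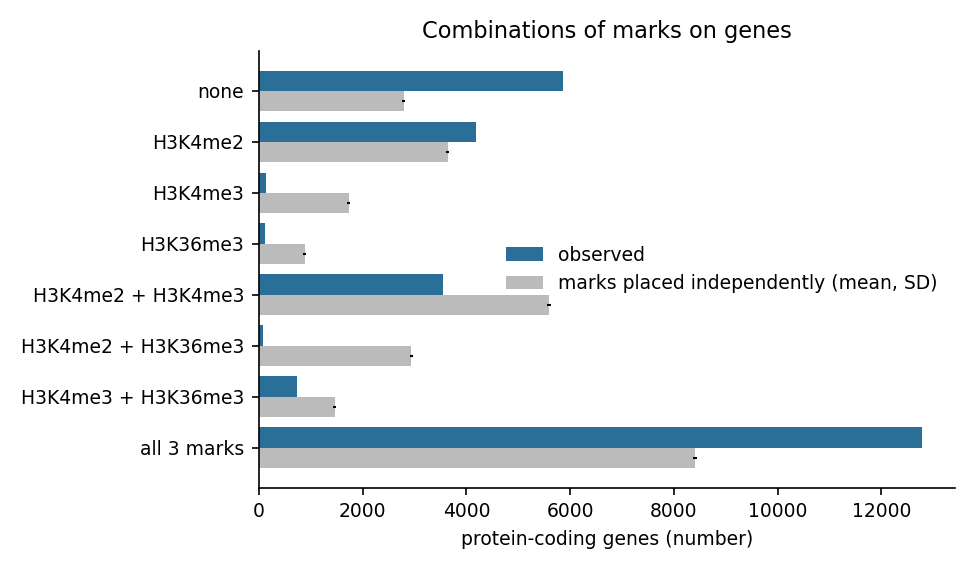
Number of protein-coding genes (horizontal axis) with each combination of marks (vertical axis), as observed and as the mean ± SD of 1000 independent placements of the marks within deciles of gene length. All 3 marks together (12778 genes) and no mark (5871 genes) exceeded the independent numbers, and H3K36me3 without H3K4me3 fell far below them when 200 bp of the gene had to be covered.

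FPA and the loci taken here as BDR genes carried H3K4me3 and H3K36me3. FPA carried H3K4me3 on chromosome 2 from 18030156 to 18031263 (TAIR10, fold 9.59) and H3K36me3 from 18027920 to 18031246 (fold 6.71) and no listed H3K4me2 peak. The 3 loci fixed beforehand as BDR genes, an assignment that rests on recall and on no source used here, all carried H3K4me3 and H3K36me3, at folds of 8.16 and 4.89 for AT5G25520, 10.7 and 6.77 for AT5G11430, and 6.93 and 5.36 for AT2G25640. The H3K4me3 and H3K36me3 peaks of AT5G11430 have their summits inside it but lie over 2 genes, so they cannot be assigned to it alone. H3K4me2 was listed at AT5G25520 (fold 2.01) and AT2G25640 (fold 4.75) and not at AT5G11430, and the comparison with length-matched genes did not pass for any mark (permutation test, adjusted p = 0.117, 1 and 0.814 for H3K4me2, H3K4me3 and H3K36me3). With 4 loci, carriage by all of them cannot pass this test, so it does not tell whether they differ from other genes. The lists do not tell in which genotype a peak on FPA or a BDR locus was present.

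Flowering time genes were mostly in the state with all 3 marks. FLC, the repressor of flowering whose level FPA controls, carried H3K4me2 on chromosome 5 from 3178323 to 3179426 (fold 5.25) with a weaker peak from 3173420 to 3173960 (fold 2.91), H3K4me3 from 3178615 to 3179415 (fold 8.90) and H3K36me3 from 3176101 to 3179402 (fold 4.71). In which genotype these FLC peaks were present cannot be told from the pooled lists. All 3 marks were found on 17 of the 24 genes of the list, among them FCA, FY, FLD, FVE and LD of the autonomous pathway and the FLC relatives FLM, MAF2, MAF3 and MAF4. SOC1, MAF5 and FD carried H3K4me2 and H3K4me3 without H3K36me3, and VIN3, which is induced by cold, carried H3K4me2 alone. The floral inducers FT and TSF and the inflorescence gene TFL1 carried none. The shares of the list, 87.5% for H3K4me2, 83.3% for H3K4me3 and 70.8% for H3K36me3, did not pass the test against length-matched genes (permutation test, adjusted p = 1 for each mark).

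Photosynthesis genes carried H3K4me3 with little H3K4me2. All 26 genes of the list carried H3K4me3, against a mean of 14.9 in 10000 random lists matched on gene length, and 20 carried H3K36me3 (mean 11.0). H3K4me2 was found on 4 of them, LHCA2, PSAD-1, PSAF and PETC, at folds of 1.89 to 2.29, against a mean of 18.8. The share with H3K4me2 was lower and those with H3K4me3 and H3K36me3 were higher than in the matched lists (two-sided permutation test, adjusted p = 0.0012, 0.0012 and 0.0027). The chlorophyll-binding protein genes LHCB2.1, LHCB3, LHCB4.1 and LHCB5 were among those with H3K4me3 and H3K36me3, and LHCB1.1, LHCB1.2, LHCB1.3 and the Rubisco small subunit gene RBCS1A were among the 6 with H3K4me3 alone. The LHCB1, LHCB2 and RBCS genes are near-identical copies that can share reads, so their own peaks are uncertain. Between the listed H3K4me2 peaks around 19 of the 22 genes without the mark, at least 1 called peak had been left out of the list, so H3K4me2 there may be weak and not absent. The state was not limited to this list, as 7 of 18 housekeeping and 10 of 48 ribosomal protein genes carried H3K4me3 and H3K36me3 without H3K4me2.

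Housekeeping and ribosomal protein genes carried both trimethyl marks in nearly every case. All 18 housekeeping genes carried H3K4me3 (matched mean 12.8, permutation test, adjusted p = 0.0094) and 17 carried H3K36me3 (matched mean 10.3, permutation test, adjusted p = 0.0048), the exception being the cyclophilin gene ROC1. H3K4me2 was found on 11 of them, among them ACT8, TUB2, TUA4 and GAPC1, and not on ACT2, ACT7, UBQ10, UBQ5 and 3 others (matched mean 14.8, permutation test, adjusted p = 0.0819), and this deficit was called among the strongest 50% of peaks (11.1% of genes, adjusted p = 0.0164), with equal numbers of peaks (11.1%, adjusted p = 0.00288) and when 50% of the gene body had to be covered (5.56%, adjusted p = 0.0288). Of 48 ribosomal protein genes recognised by name, 47 carried H3K4me3 and 47 carried H3K36me3, against matched means of 28.7 and 21.9 (permutation test, adjusted p = 0.0012 for both), with RPL12-B the exception for both marks, and 37 carried H3K4me2 (mean 35.5, adjusted p = 0.886). Among the strongest 50% of peaks, H3K4me2 was on 16.7% of the ribosomal protein genes and below the matched lists (permutation test, adjusted p = 0.0064).

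Genes of the list named H3K4 and H3K36 methylation machinery, of RNA polymerase II and of 3′ end processing carried the marks nearly throughout. The methylation list is not limited to enzymes that add these marks. It also holds, for instance, LDL1 and JMJ14 for demethylation and SPT16 and SSRP1 for a histone chaperone. All 21 genes of the methylation list carried H3K4me3 and H3K36me3, and 20 carried H3K4me2, the exception being MRG1, a reader of H3K36 methylation. The share with H3K36me3 was above the matched mean of 14.9 (permutation test, adjusted p = 0.0059), while the shares with H3K4me3 (mean 17.3, adjusted p = 0.0724) and H3K4me2 (mean 18.9, adjusted p = 0.886) did not pass. All 13 genes for RNA polymerase II and 3′ end processing, among them NRPB1, NRPB2, CPSF30 and CPSF73-I, carried all 3 marks. This did not pass the test (permutation test, adjusted p = 0.814, 0.344 and 0.076 for H3K4me2, H3K4me3 and H3K36me3), where matched genes carried the marks at 91.6%, 85.1% and 74.3%. Under other rules the list was called: for H3K4me3 and H3K36me3 among the strongest 50% of peaks, for H3K36me3 with 50% of the gene body, and for H3K4me3 with equal numbers of peaks. Of the 13 circadian clock genes, 13 carried H3K4me3, and 12 each carried H3K4me2 and H3K36me3, with LNK1 and ELF4 the exceptions (permutation test, adjusted p = 0.0529, 0.886 and 0.0739). Their H3K4me3 excess was called with a summit inside the gene, with equal numbers of peaks and with 50% of the gene body. With 50% of the gene body their H3K4me2 excess was called too. The H3K36me3 excess of the methylation list was not called among the strongest 50% of peaks, where 57.1% of its genes carried the mark (permutation test, adjusted p = 0.213).

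Polycomb-repressed developmental regulators and seed maturation genes carried the trimethyl marks seldom or not at all. Polycomb-repressed is the name of the fixed list, and no mark of Polycomb repression was profiled in this series. Of 26 Polycomb-repressed regulators, 2 carried H3K4me3, the meristem gene KNAT1 (fold 3.20) and the floral regulator LFY (fold 3.85), and 0 carried H3K36me3, against matched means of 19.9 and 16.6 (permutation test, adjusted p = 0.0012 for both). H3K4me2 was found on 19 of them, among them AG, KNAT1, KNAT2 and LEC1, and not on STM, PHE1, MEA, WOX5 and 3 others. This share of 73.1% was not called against the matched 86.2% (permutation test, adjusted p = 0.153). With equal numbers of peaks per list, the H3K4me2 deficit of these regulators was called. Of 13 seed maturation genes, 0 carried H3K4me3 (matched mean 5.42, permutation test, adjusted p = 0.0027) or H3K36me3 (mean 3.75, adjusted p = 0.0245), and CRU1, CRU2 and EM1 carried H3K4me2 at folds of 2.02 to 2.33 (mean 7.38, adjusted p = 0.036). Both lists' deficits of H3K4me3 were not called when 50% of the gene body had to be covered, where the matched shares were 12.4% and 24.8% (permutation test, adjusted p = 0.0997 and 0.0756). Among the strongest 50% of peaks, 0 of the seed maturation genes carried H3K4me3 or H3K36me3, yet neither deficit was called (permutation test, adjusted p = 0.176 for H3K4me3 and 0.368 for H3K36me3). A share of 0 cannot fall further when peaks are dropped, so these lost calls do not show a weaker deficit. The H3K4me2 deficit of the seed maturation genes was not called when a summit had to lie in the gene (permutation test, adjusted p = 0.0561).

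Stress-inducible genes and markers of particular cell types carried H3K36me3 less often than length-matched genes. Of 19 stress and defence genes, 14 carried H3K4me2, 7 carried H3K4me3 and 3 carried H3K36me3, and the share with H3K36me3 was below the matched mean of 8.79 (permutation test, adjusted p = 0.0154) while H3K4me3 (mean 11.4, adjusted p = 0.0841) and H3K4me2 (mean 14.0, adjusted p = 1) did not pass. The H3K4me3 deficit of the stress list was called among the strongest 50% of peaks and with equal numbers of peaks per list. The 3 with all marks were the heat shock gene HSP101, DREB2A and WRKY33, RD29A and CBF1 were among those with H3K4me2 and H3K4me3, PR5, RD29B and COR15A were among those with H3K4me2 alone, and PR1, PR2, KIN1 and PDF1.2 were among the 5 with none. Of 13 markers of the root, root hairs, stomatal lineage and trichomes, 4 carried H3K4me3 (SCR, SHR, GL2 and TMM) and 2 carried H3K36me3 (SCR and GL2), against matched means of 9.39 and 7.74 (permutation test, adjusted p = 0.009 and 0.0059), and 8 carried H3K4me2 (mean 10.8, adjusted p = 0.136). The H3K4me3 and H3K36me3 peaks counted for GL2 lie over 2 genes and have their summits outside GL2. The deficits of the cell type markers depended on the rule: neither was called among the strongest 50% of peaks (H3K4me3 on 15.4% and H3K36me3 on 7.69% of genes, permutation test, adjusted p = 0.195 and 0.176), and that of H3K4me3 turned round when 50% of the gene body had to be covered (23.1% of genes against 17.6%, adjusted p = 0.95).

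**Figure D2:**
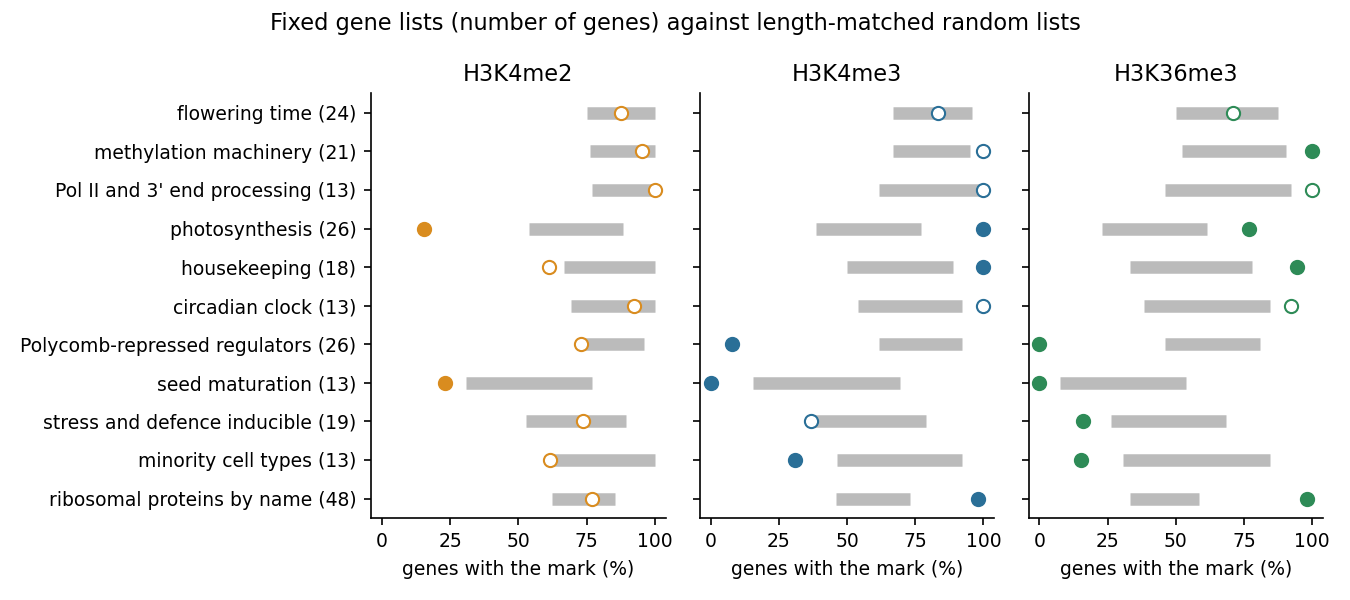
Share of each gene list, without the 4 study loci, with a peak of each mark (points, percent of the genes whose number stands in brackets), beside the central 95% of 10000 random lists matched on gene length (grey bars). The markers of root, root hair, stomatal lineage and trichome appear as minority cell types, the name of the fixed list. Filled points passed an adjusted p of 0.05; photosynthesis genes lay far to the left for H3K4me2 (4 of 26) and at 100% for H3K4me3, and Polycomb-repressed and seed maturation genes lay near 0 for H3K4me3 and H3K36me3.

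Within genes, the H3K4me3 and H3K36me3 summits coincided and the H3K4me2 summit lay further inside. In 12686 genes with a single summit of both marks, the H3K4me3 and H3K36me3 summits were a median of 11 bp apart. The H3K36me3 summit lay a median of 2 bp further from the nearer gene end (95% interval 2 to 2). H3K4me2 summits lay a median of 524 bp from the nearer gene end (517 to 531), against 300 bp for H3K4me3 (297 to 303) and 336 bp for H3K36me3 (332 to 340). In the 14460 genes with both H3K4 marks, the H3K4me3 summit was 292 bp nearer to the gene end than the H3K4me2 summit (paired median −292 bp, −295 to −290). When 10988 genes were read from the end nearer their H3K4me3 summit, H3K4me2 lay beyond H3K36me3 in 86.9% of genes, by a median of 304 bp (302 to 306), with the same sign on all 5 chromosomes. Of the summits in genes read this way, 99.5% for H3K36me3 and 94.6% for H3K4me2 lay on the H3K4me3 side of the gene's middle. The annotation used here gives no strand, so the end nearer the H3K4me3 summit stands in for the start of the gene. These positions hold for summits: for peak midpoints H3K36me3 lay 364 bp further in than H3K4me3 (355 to 373), H3K4me3 minus H3K4me2 was −181 bp (−187 to −176), and the order of H3K36me3 and H3K4me2 turned round (H3K4me2 minus H3K36me3 −158 bp, −166 to −149). In genes with neighbours at least 1 kb away, H3K4me3 minus H3K4me2 was −137 bp (−160 to −94.0).

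**Figure D3:**
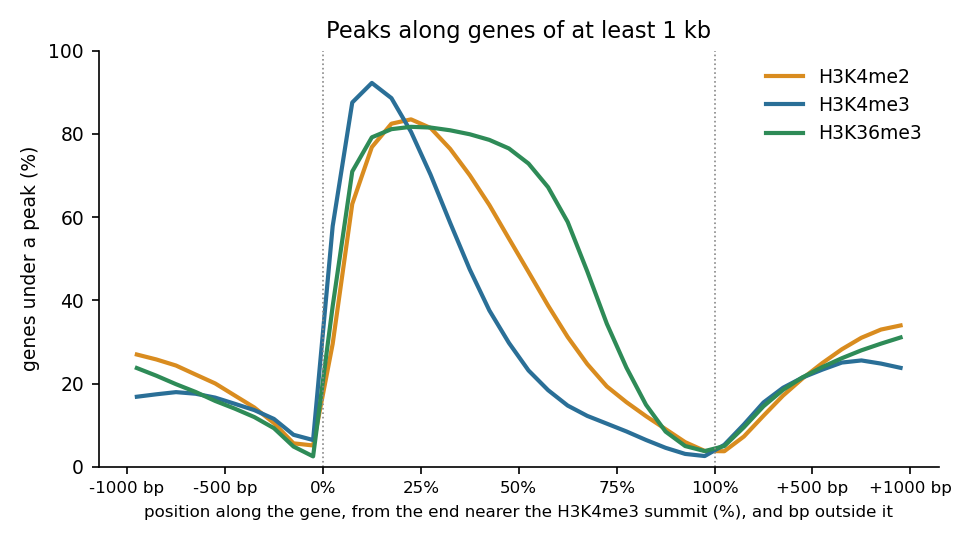
Share of 14270 genes of at least 1 kb (vertical axis, percent) whose sequence lies under a peak of each mark, along the gene in percent of its length from the end nearer the H3K4me3 summit, and up to 1000 bp outside it (horizontal axis). H3K4me3 peaks at 92.3% of genes near the start, H3K36me3 covers 79.9% of genes at a position of 37.5% where H3K4me3 covers 47.4%, and all 3 marks fall below 5% at the last part of the gene. The high H3K4me3 share at the left and the low one at the right follow in part from the choice of the start.

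FPA acts in 3′ end formation, and peaks over gene ends were compared between genes with different neighbours. Taking as the end the one away from the H3K4me3 summit, and sorting genes by whether the next gene pointed the same way (tandem) or towards it (convergent), 3.92% of 3950 tandem and 2.94% of 2043 convergent genes with H3K4me3 had the end base under an H3K4me3 peak (difference 0.987 percentage points, 95% interval −0.325 to 2.13). With the next gene under 500 bp away, the shares were 5.85% and 3.69% (difference 2.15, 0.118 to 3.93). Both the end and the orientation of the next gene are taken from H3K4me3 summits, so low H3K4me3 shares at the end and higher ones beside a close tandem gene follow in part from that choice. For H3K36me3 the order was the opposite, with 2.56% of 3246 tandem and 4.06% of 1624 convergent genes (difference −1.51, −2.83 to −0.242), and 2.37% and 5.36% when the next gene was under 500 bp away (difference −3.00, −5.01 to −1.20). H3K4me2 lay over 3.90% of tandem and 3.83% of convergent ends (difference 0.0665, −1.18 to 1.26). Close genes exceeded genes with a neighbour at least 2 kb away for H3K4me3 in tandem (5.85% against 1.27%, difference 4.57, 3.26 to 5.73) and for H3K36me3 in convergent pairs (5.36% against 0.948%, difference 4.41, 2.42 to 6.55). These differences depend on the rule: in genes of at least 2 kb the H3K36me3 difference between tandem and convergent genes was gone (0.0865, −1.09 to 1.23), and when a peak had to cover 50% of the last 500 bp the H3K4me3 difference turned round (−2.79, −4.92 to −0.834).

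Wider peaks had higher −log10 p in every list. Spearman's rho between width and −log10 p across peaks was 0.368 for H3K4me2 (95% interval 0.356 to 0.380), 0.280 for H3K4me3 (0.264 to 0.295) and 0.314 for H3K36me3 (0.298 to 0.33), where peaks are not independent replicates. Among the strongest 50% of peaks it was 0.164, 0.0576 and 0.0270. H3K36me3 width followed gene length most closely, as the median gene length rose from 1615 bp in the narrowest quintile of H3K36me3 peaks to 4685 bp in the widest. For H3K4me2 the gene length rose from 1595 to 2973 bp. For H3K4me3 it rose from 2165 bp in the narrowest quintile to 2468 bp in the next and then stayed between 2510 and 2540 bp, while the peak's share of the gene rose from 27.0% to 63.5%.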

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

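Of 360 values recomputed under alternatives, 283 counted as unchanged, 36 moved, 22 became stronger, 10 weaker and 9 reversed. Unchanged meant, for a result with a test, the same side of the threshold and, where either value passed it, the same direction. A result that passed in neither case counted as unchanged whatever its direction. Reversed meant a change of direction where either value passed, whether or not the new value did. Stronger and weaker meant a call gained or lost. For the span, the shares of genes and the count of calls it meant within 1.5 times, and for widths within the interval. The overlaps between marks (54 values) and the relation of width and −log10 p (9 values) kept their direction and their call, though not their size: with 50% of the peak covered, 55.9% of H3K36me3 peaks overlapped H3K4me3 and 69.0% overlapped H3K4me2. Merging touching peaks was run for widths and span, 250 kb blocks for summit positions and gene ends, and leaving out a chromosome for overlaps, and none of these changed a call or counted as moved. Equal numbers of peaks per list, the fold in place of −log10 p and distances that need no strand were chosen after seeing the data. Distances from the annotated start, the strand of the next gene and transposable element genes were not run, since the gene table gives no strand and no such class. Read depth is unknown and limits weak peaks most, so absence of a peak is no measure of absence of a mark. The strongest 50% and the equal numbers hold fewer peaks by construction, and 50% of the gene body is a stricter rule by construction; for the other changes the cause was not tested.

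With the strongest 50% of peaks, median widths for H3K4me2, H3K4me3 and H3K36me3 were 1110, 890 and 1771 bp, the span covered 11.7%, 7.49% and 12.0%, and the genes with the mark 40.7%, 33.2% and 25.7%. No mark was then on 39.1% of genes, H3K4me2 alone on 25.1%, H3K4me2 with H3K4me3 on 5.74%, H3K4me3 with H3K36me3 on 14.1% and all marks on 9.08%. H3K4me2 was at 44.3% of H3K4me3 and 38.3% of H3K36me3 peaks, 22.4% of H3K4me2 peaks overlapped H3K36me3, and rho of width and −log10 p fell to 0.164, 0.0576 and 0.0270. Among the lists, calls gained were H3K4me3 (92.3%) and H3K36me3 (76.9%) for RNA polymerase II and 3′ end genes, H3K4me2 for housekeeping (11.1%) and H3K4me3 for stress genes (5.26%). Calls lost were H3K36me3 for the methylation list (57.1%) and H3K4me3 (0%) and H3K36me3 (0%) for seed maturation. Those of H3K4me3 (15.4%) and H3K36me3 (7.69%) for the cell type markers were also lost. H3K4me2 on ribosomal protein genes reversed (16.7%).

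With 50% of the gene body, H3K4me2 was on 34.3% and H3K4me3 on 19.05% of genes, no mark on 38.1%, H3K4me2 with H3K4me3 on 5.88%, all marks on 8.54%, H3K36me3 alone on 23.0% and with H3K4me2 on 7.29%. Calls gained were H3K36me3 for RNA polymerase II and 3′ end genes (92.3%), H3K4me2 for housekeeping (5.56%), and H3K4me2 (53.8%) and H3K4me3 (30.8%) for clock genes. H3K4me3 was no longer called for Polycomb-repressed (0%) and seed maturation genes (0%) and reversed for the cell type markers (23.1%).

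With a summit inside the gene, H3K4me3 was called for the methylation list (100%) and clock genes (100%) and H3K4me2 was not for seed maturation (23.1%). Against unmatched random lists, H3K4me3 was called for the methylation list (100%). Calls were also gained for H3K4me3 (100%) and H3K36me3 (100%) in RNA polymerase II and 3′ end genes. Clock genes gained H3K4me3 (100%) and H3K36me3 (92.3%), and H3K4me3 for the cell type markers was lost (30.8%).

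With equal numbers of peaks, H3K4me2 was on 47.0% of genes, H3K4me3 with H3K36me3 on 19.9%, H3K4me2 with H3K4me3 on 2.47% and all marks on 26.8%. Calls gained for H3K4me3 were the methylation list (100%) and RNA polymerase II and 3′ end (100%), clock (100%) and stress genes (21.1%). Those gained for H3K4me2 were housekeeping (11.1%) and Polycomb-repressed genes (30.8%), and H3K4me2 on ribosomal protein genes reversed (18.8%).

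With peak midpoints, H3K36me3 minus H3K4me2 reversed to 135 bp from the nearer end, and H3K4me2 minus H3K36me3 to −158 bp from the H3K4me3 end, while H3K36me3 minus H3K4me3 was 364 bp and H3K4me3 minus H3K4me2 −181 bp. With neighbours at least 1 kb away, H3K36me3 minus H3K4me3 was 1 bp (0 to 2) and H3K4me3 minus H3K4me2 −137 bp. With a peak over 50% of the last 500 bp, tandem minus convergent for H3K4me3 reversed to −2.79 points under 500 bp and −3.01 at all distances. In genes of at least 2 kb it was 2.28 for H3K4me3 at all distances, and reversed for H3K36me3 to 0.0865 under 500 bp and 0.120 at all distances.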

Other observations

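The gene families and the biotypes were examined after the data were seen, and so were the tests of reads shared between copies, of the selection of peaks, and of the peaks over gene ends.

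Gene families defined by a shared symbol prefix fell into groups with opposite states. Of 62 families with 20 or more members, tested for 3 marks against length-matched random genes, 75 of 186 tests passed an adjusted p of 0.05, with H3K36me3 higher in 8 families and lower in 23. The EMB genes, named for embryo-defective mutants, carried H3K4me2, H3K4me3 and H3K36me3 in 153, 156 and 153 of 160 members (matched means 135, 120 and 99.96, permutation test, adjusted p = 8.27e-04 for each), and the VPS genes of vacuolar protein sorting in 29, 28 and 26 of 29 members (means 24.3, 21.2 and 17.5, adjusted p = 0.0276, 0.00834 and 0.00304). The LCR genes for small cysteine-rich proteins carried the marks in 3, 2 and 1 of 81 members (means 31.4, 19.1 and 11.2, permutation test, adjusted p = 8.27e-04 for each), and the CHX cation exchanger genes in 11, 3 and 2 of 23 (means 20.5, 18.5 and 15.8, adjusted p = 8.27e-04 for each). The CYP cytochrome P450 genes were closer to the matched lists for H3K4me2, with 160 of 229 members (mean 188), than for H3K36me3, with 43 (mean 131, permutation test, adjusted p = 8.27e-04 for both). The AGP genes for arabinogalactan proteins carried more H3K4me2 (23 of 30, mean 15.4, permutation test, adjusted p = 0.0168) and H3K4me3 (20, mean 10.0, adjusted p = 0.00158) than matched genes, and H3K36me3 on 7 of them (mean 5.93) did not pass (adjusted p = 0.893). The ERF genes of ethylene response factors had a like pattern, with H3K4me2 on 22 of 25 (permutation test, adjusted p = 0.0377), H3K4me3 on 21 (adjusted p = 0.00232) and H3K36me3 on 9 (adjusted p = 0.977).

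Among genes that code for no protein and lie at least 500 bp from protein-coding genes, the 118 snoRNA genes carried H3K4me3 in 78.8%, H3K36me3 in 67.8% and H3K4me2 in 41.5% of cases, and the 3465 pseudogenes in 1.59%, 0.981% and 3.29%. Of 170 tRNA genes, 17 carried H3K36me3, 0 carried H3K4me3 and 1 carried H3K4me2. The 17 lay on chromosome 1, under 4 H3K36me3 peaks from 10089286 to 10095052 (fold 3.34), 10099232 to 10102838 (fold 4.64), 10108600 to 10111635 (fold 6.37) and 17156831 to 17164774 (fold 4.42). An array of 81 tRNA genes on the same chromosome, from AT1G56730 to AT1G57530, had 0 under a peak of any mark. These values had no test.

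Photosynthesis genes carried H3K4me3 but seldom H3K4me2, with 4 of 26 members or 15.4% against a matched range of 53.8% to 88.5%, which argues against gene length as the cause. Reads shared between near-identical copies are argued against as the whole cause, since without the LHCB1, LHCB2 and RBCS genes 4 of 18 members (22.2%) carried H3K4me2 against a matched range of 50.0% to 88.9%. The selection of peaks stays open: the 22 members without H3K4me2 lie in 18 gaps between listed peaks, of which 3 (16.7%, exact 95% interval 3.58 to 41.4) had no called peak left out, beside 7.36% of all 870 genes with H3K4me3 and no H3K4me2, and a dropped peak in such a gap may lie on the gene or beside it. Genes with H3K4me3 and no H3K4me2 had a higher H3K4me3 fold than genes of like length with both (0.614, 0.435 to 0.799). That difference may be part of the pattern. Without length matching, the median fold was 9.17 in the 22 members, 9.18 in all 870 genes with H3K4me3 and no H3K4me2, and 8.99 in genes with both marks. These unmatched medians do not tell whether the members share the difference. No biological explanation was tested, as the lists give no value per genotype and no transcript levels.

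H3K4me3 was on 2 of 26 Polycomb-repressed and 0 of 13 seed maturation genes, and H3K4me2 on 19 and 3 of them. No called H3K4me3 peak was left out around 11 of 13 seed maturation genes, but these 13 lie in 10 gaps between listed peaks, 8 of them without a peak left out (80.0%, exact 95% interval 44.4 to 97.48), which leaves the selection of peaks open for the list. The selection of peaks stays open for the Polycomb list, where 8 of 24 gaps had no peak left out (33.3%, 15.6 to 55.3). The share was 44.9% of all genes without H3K4me3 and 25.0% of those that carried H3K4me2. H3K4me2 on 7 of 22 carriers (31.8%, 13.9 to 54.9) was in the stronger part of the list, which leaves open whether these peaks are mostly near the threshold. Among members without H3K4me3, 17 of 24 (70.8%) carried H3K4me2 inside the range of length-matched genes without H3K4me3 (mean 54.7%), so it cannot be told apart whether H3K4me2 is particular to the Polycomb list, and no biological explanation was tested.

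Gene ends lay under an H3K4me3 peak more often when the next gene was close, and under an H3K36me3 peak for convergent pairs, while the intervals of close minus far included 0 for H3K4me2 in tandem (0.515, −1.39 to 2.18) and convergent pairs (−0.0498, −2.65 to 2.46) and for H3K36me3 in tandem (0.884, −0.533 to 2.16). For H3K4me3 in tandem, short genes do not account for it, as the difference was 5.18 percentage points (4.04 to 6.44) in genes of at least 2 kb, and 112 of 124 such peaks (90.3%) had their summit outside the gene, which cannot count for a source because H3K4me3 summits also define the end and the orientation. For convergent pairs the summit lay outside the gene in 18 of 57 H3K36me3 peaks (31.6%, exact 95% interval 19.9 to 45.2). This cannot decide whether a peak centred on the neighbour is the usual source. The genes were chosen for carrying H3K36me3 and for an H3K4me3 summit inside, and H3K36me3 summits mostly lie close to H3K4me3 summits. Short genes covered by 1 peak from end to end may account for the H3K36me3 pattern, since in genes of at least 2 kb it shrank from 4.41 to 1.67 percentage points (0.849 to 2.58), with 13 of 780 close and 0 of 159 far genes (Fisher's exact test, two-sided p = 0.141). No biological explanation was tested.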
